A study of Drosophila melanogaster with 4 samples.

How the data were processed

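Wild-type Oregon-R Drosophila melanogaster larvae of the third instar were assayed by ChIP-seq with an antibody against histone H1. Per the labels' protocols, tissue was homogenised and crosslinked with formaldehyde, chromatin was sonicated, and DNA was recovered after immunoprecipitation. The 4 samples of the series are 2 H1 ChIP and 2 input samples, numbered as replicates 1 and 2 in the labels. The labels do not say that the replicates came from separate cultures, so the spread between them may be technical. Each ChIP sample had a list of enriched regions, and 1 further list, called combined here, is a replicate set of the whole series. The input libraries were not analysed here.

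Each deposited list gives the start and end of regions of enrichment and a score for each region, as the authors computed it. Per the file headers the positions are on FlyBase Release 5, and lengths of 14 sequences are given there. Bowtie 0.12.7 is named in the submitters' processing notes, with no role stated. The region caller, its threshold, the use of the input, the read depth and the way the replicates were combined are not given in the sources used here. A different threshold would change the number of regions, so counts of regions are compared within a list, and between lists only as values. Without depth, differences between the replicates in number of regions cannot be set against sequencing depth, and no counting interval is given for a score.

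The scale of the deposited score was examined in the values. In each list 2 raised to the score was a constant of that list times a ratio of whole numbers (denominator up to 5000, relative tolerance 1e-11) for 100% of regions, while at most 16 regions of a list met this after the scores were shifted. Scores were therefore treated as log2 ratios. The sources do not say what the whole numbers count, the ratios are in lowest form, and the constant is fixed only up to a factor, so no read counts were derived. The constant was chosen in 3 ways, by the steps of the highest scores, by the lowest median denominator and by the lowest median product of the terms. Upper term and lower term mean the numerator and denominator of the ratio in lowest form. They are not read counts and vary with the constant: the median lower term of replicate 1 was 129, 67 and 179 with the 3 ways. The later 2 ways were added after values from earlier ones had been seen, so values are given over all 3. A score is the authors' own value and was used to describe, rank or filter regions within a list.

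Overlap meant at least 1 bp shared. Chance was set by rotating the regions of each sequence together by a random multiple of 100 bp, with 100000 draws and a two-sided p, whose smallest value is 1e-05. In a test on simulated data with 3779 regions and 2000 draws for the comparison of replicate 1 with replicate 2, 1 of 30 unrelated sets gave p under 0.05, and all 10 sets with 10% of regions planted as shared did, with a mean excess of 7.70%. Simulated regions were scattered evenly along each sequence. The simulation therefore does not show how rotation behaves where both lists are dense in the same parts of a chromosome. Shares carry 95% Wilson intervals, which cover counting of regions only. Covered shares were taken over whole sequence lengths in the headers, with no correction for copy number or for sequence where reads cannot be placed. Rotation could also move regions into such sequence. The autosomal arms are 2L, 2R, 3L and 3R. Placed heterochromatin is 2LHet, 2RHet, 3LHet and 3RHet. Position along an arm was tested with Spearman's rho over 10 equal windows and 100000 permutations, adjusted by Benjamini-Hochberg over 5 arms. Score correlations used 1000 bootstrap draws.

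Regions named in the text are, among combined regions that overlap both replicates, the 10 with the highest score and the 10 longest, a rule set before the data were examined, as were the tests and most other settings. Those settings were scores at or above the median of each list, a minimum length of 1000 bp, joining regions less than 1000 bp apart, overlap of 50%, the main chromosome sequences alone, random placement with 1000 draws, 20 windows per arm, the mean in place of the highest score, and leaving out each replicate. Regions of at least 2000 bp, heterochromatic and unplaced sequences alone, and regions moved by up to 50 kb with 1000 draws were added after seeing the data, as were the score limits and the 100 kb windows.

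Coverage of gene features and gene lists and the base composition of regions were planned and not analysed here, because the gene table used here is of Release 6 and the region lists are of Release 5, and positions were not converted. Regions are thus given by position alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.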

Results

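H1 is the linker histone, which binds nucleosomes and the DNA between them. Its distribution was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type Oregon-R larvae of Drosophila melanogaster at the third instar, the last larval stage. The series held 2 H1 ChIP samples and 2 input samples. The values reported here come from the enriched regions of ChIP replicate 1, of ChIP replicate 2 and of 1 combined table of the series; the input libraries were not analysed here. Positions are those of Release 5 of the genome. The read depth of the samples is unknown from these region lists.

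H1-enriched regions covered a small part of the genome in each replicate and a much larger part in the combined table. Replicate 1 held 3779 regions over 6.39 Mb, which is 4.57% of the 139.7 Mb of sequence with regions in any list. Replicate 2 held 4665 regions over 8.14 Mb, or 5.83%. The replicate mean was 4222 ± 626 regions and 7.27 ± 1.24 Mb (SD, n = 2). The combined table held 18812 regions over 38.7 Mb, or 27.7% of the sequence, 4.98 times the regions of replicate 1 and 4.03 times those of replicate 2.

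Regions were mostly short, with modest scores. The median length was 1542 bp in replicate 1, 1579 bp in replicate 2 and 1625 bp in the combined table, and the longest regions measured 5593, 7731 and 22953 bp. The shortest measured 1301 bp in each replicate and 1001 bp in the combined table. The authors' score, which behaves as a log2 ratio, had medians of 0.54, 0.58 and 0.39, equal to ratios of 1.45, 1.49 and 1.31. The lowest scores were 0.25, 0.26 and 0.17. Across regions within a list, longer regions had slightly higher scores in the replicates (Spearman's rho of 0.26 and 0.27), with rho of 0.06 in the combined table. Regions are not independent replicates, and 2 samples allow no test between the replicates.

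The replicates marked the same places more often than chance placement did, although most regions of each had no partner in the other. Of the 3779 regions of replicate 1, 1189 overlapped a region of replicate 2 by at least 1 bp, a share of 31.5% (95% Wilson interval 30.0 to 33.0%), against 12.6% after rotation of the regions along their chromosome sequence. Of the 4665 regions of replicate 2, 1182 overlapped replicate 1, a share of 25.3% (24.1 to 26.6%), against 10.3%. By length, 10.0% of the sequence covered in either replicate was covered in both, 3.28 times the 3.06% given by rotation. When regions were instead moved by up to 50 kb, a setting chosen after seeing the data that keeps the regional density, chance was 5.09% and the excess 1.97 times by length, and 1.59 times for the regions of replicate 1. The share covered in both was 12.3% on 3R and 4.44% on the X, against 4.04% and 1.35% for independent placement at their coverage, an excess of 3.05 and 3.30 times. On chromosome 4 and XHet, with few regions, it was 0, against 0.293% and 0.482%.

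**Figure D1:**
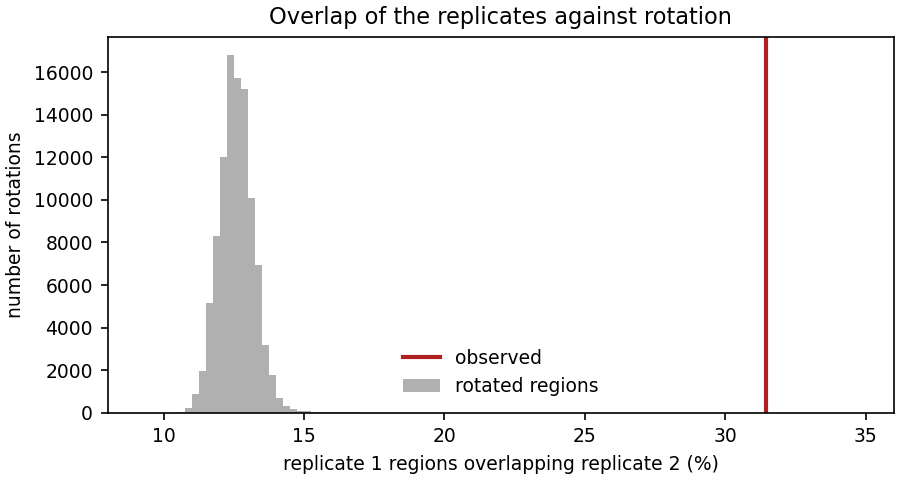
The horizontal axis gives the share of replicate 1 regions that overlapped a region of replicate 2, in percent, and the vertical axis the number of rotations. Grey bars show 100000 random rotations, with a mean of 12.6%, and the red line the observed 31.5%.

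The overlap by length and both shares of regions, over all sequences, each had a two-sided permutation p of 1e-05 by rotation, the smallest that 100000 draws can give. Single chromosomes were not tested. The p describes these 2 libraries, since regions are not replicates, and the labels do not say that the replicates came from separate cultures, so the spread between them may be technical. The observed share depended on what entered: requiring 50% of both regions left 17.9% of replicate 1 and 14.5% of replicate 2, and taking scores at or above the median of each list left 20.3% and 16.5%, all above their chance values.

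Nearly all regions of the replicates overlapped the combined table by at least 1 bp, while most combined regions had no counterpart in either replicate. The combined table overlapped 98.6% of the regions of replicate 1, against 48.1% by rotation, and 97.9% of those of replicate 2, against 47.1%. Requiring 50% of both regions left 56.6% and 59.8%. In the other direction, 18.4% of combined regions overlapped replicate 1 and 22.7% overlapped replicate 2, against 10.7% and 12.9%. Regions supported by both replicates numbered 1263, or 6.71%, with a median length of 4099 bp, while 12352, or 65.7%, overlapped neither, with a median of 1355 bp. Of the longest 10% of combined regions, 60.0% overlapped replicate 1 and 67.4% replicate 2, compared with 1.38% and 2.39% of the shortest 10%. The shortest 10% measured 1001 to 1051 bp, below the 1301 bp of the shortest region in either replicate. The lists thus differ in their shortest regions, and their thresholds are unknown. Counts of regions without a counterpart therefore do not compare regions known to be called alike.

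The permutation p by rotation was 1e-05 for each of these 4 comparisons, the smallest possible. With regions moved within 50 kb, chosen after seeing the data, the excess was from 1.30 to 1.56 times. The combined table bears on the same libraries, so the overlap is not independent evidence. Longer regions also meet other regions more often by chance.

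Among the 1263 combined regions found in both replicates, the 10 with the highest score lay mainly in heterochromatic or unplaced sequence: 5 on 3LHet, 2 on U, and 1 each on 2L, 2R and 3R. The highest was on 2R at 1457552 to 1461164, with a score of 0.83, a ratio of 1.77. It was followed by U at 5921500 to 5923916 with 0.74, 2L at 20107090 to 20111584 with 0.73, 3LHet at 1095566 to 1097674 with 0.72 and 3R at 23613152 to 23617708 with 0.66. The other 5 scored from 0.61 to 0.63.

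The 10 longest of these regions lay on the autosomal arms, 4 on 2L, 3 on 3R, 2 on 3L and 1 on 2R. The longest, on 2R at 1715064 to 1738016, measured 22953 bp with a score of 0.44, and replicates 1 and 2 covered 21.8% and 5.81% of it. The next, on 3R at 23620292 to 23640846, measured 20555 bp with a score of 0.48, and was covered to 37.4% and 65.5%. The regions on 3L at 5692540 to 5710388, on 2L at 4735050 to 4752348 and on 3R at 19385918 to 19402552 measured 17849, 17299 and 16635 bp. Whether these regions hold genes was not analysed here.

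The score of a region in one replicate was related, though not closely, to its score in the other. Over the 1263 shared regions, Spearman's rho between the highest overlapping scores was 0.33 (bootstrap 95% interval 0.28 to 0.38). It was 0.27 over the 1161 regions of the autosomal arms, 0.18 over the 65 of the X and 0.51 over the 31 of placed heterochromatin. With the mean in place of the highest score, rho was 0.29 over all shared regions and 0.23 on the autosomal arms. These are correlations across regions, which are not independent replicates.

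Called H1 regions were sparse on the X and chromosome 4 compared with the large autosomal arms. The shares are of whole sequence lengths, with no correction for copy number or for sequence where reads cannot be placed. The arm 3R was covered to 7.20% in replicate 1 and 8.42% in replicate 2, and the 4 autosomal arms together to 5.87% and 7.05%. The X was covered to 2.54% and 2.80%, a ratio to the autosomal arms of 0.414 ± 0.0247 (SD, n = 2). Chromosome 4, a small and largely heterochromatic chromosome, was covered to 0.525% and 0.659%, with 5 and 6 regions and a ratio of 0.0914 ± 0.00288 (SD, n = 2). In the combined table the ratios were 0.589 for the X and 0.186 for chromosome 4.

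Placed heterochromatin of chromosomes 2 and 3 differed between the replicates. It was covered to 1.22% with 65 regions in replicate 1 and to 5.89% with 293 regions in replicate 2, ratios to the autosomal arms of 0.208 and 0.834 and a mean of 0.521 ± 0.443 (SD, n = 2). In replicate 2, 3LHet was covered to 6.86%, above the 6.77% of 2L. The combined table gave 18.7% and a ratio of 0.565. With scores at or above the median of each list the ratios were 0.303 in replicate 1, 1.40 in replicate 2, above the autosomal arms, and 0.973 in the combined table. The unplaced sequence U was covered to 0.280%, 1.74% and 6.43%. No region of replicate 1 and 2 regions of replicate 2 lay on YHet.

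**Figure D2:**
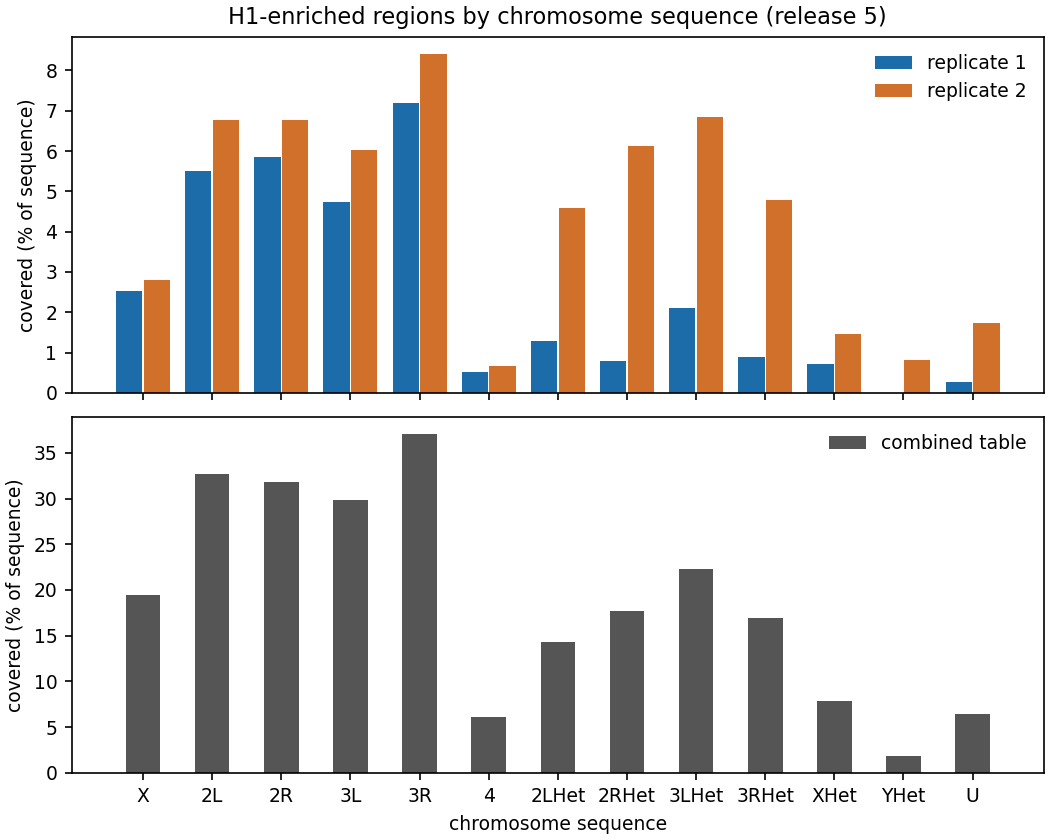
The vertical axes give the share of each chromosome sequence covered by H1-enriched regions, in percent, for the replicates (upper panel) and the combined table (lower panel, another scale). Coverage of the X was 2.54% and 2.80% in the replicates and that of 3R 7.20% and 8.42%.

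No test was made between chromosomes, since an exact permutation test over 2 replicates cannot reach the threshold. The X ratio rested on the regions that entered: it was 0.690 with scores at or above the median of each list, and 1.02 in the combined table, while with regions of at least 2000 bp, an alternative chosen after seeing the data, it was 0.248. Chromosome 4 then held no region in either replicate.

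The X differed from the autosomal arms in score as well as in number. Per Mb, the X held 0.469 times the regions of the autosomal arms in replicate 1, but 1.86 times as many at scores of at least 0.6. In replicate 2 these ratios were 0.425 and 0.974, with 3.17 at scores of at least 0.75 and 0.760 at 0.85, where 3 regions of the X were left. In the combined table the ratio was 0.727 with all regions, 3.61 at scores of at least 0.5 and 0.990 at 0.7. The X thus held more regions per Mb at intermediate scores, and not at the highest scores of replicate 2 and the combined table. These score limits were chosen after seeing the data, and a score is the authors' own value, used within its list.

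**Figure D3:**
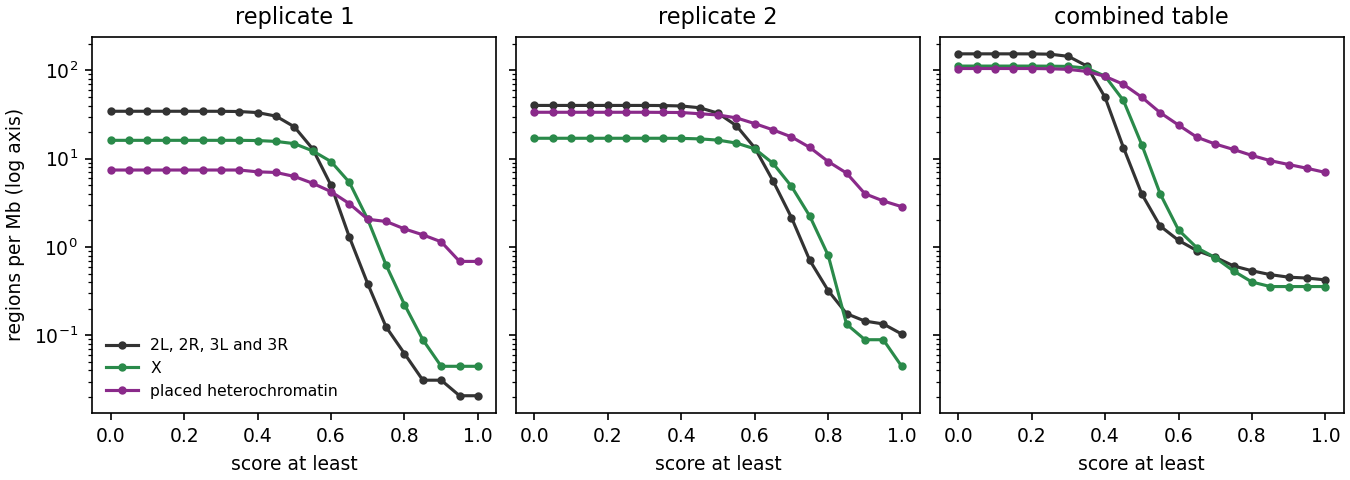
Regions per Mb on a log axis against the lowest score admitted, for the autosomal arms, the X and placed heterochromatin, with 1 panel per list. In replicate 1 the ratio of the X to the autosomal arms was 0.469 with all regions and 1.86 at scores of at least 0.6.

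Along the arms, coverage declined from the telomere towards the centromere on 3R in the replicate mean, and on no other arm past the threshold. Spearman's rho over 10 windows was -0.84 on 3R (permutation p = 0.00352, adjusted p = 0.0176 by Benjamini-Hochberg over 5 arms), -0.56 on 2R, -0.49 on 2L, -0.20 on the X and -0.01 on 3L. The second window of 3R from the telomere, at 22324044 to 25114548, was the densest of that arm in each list, with 11.1%, 14.9% and 51.1% covered in replicate 1, replicate 2 and the combined table. The third window of 2R was covered to 8.81%, 11.4% and 45.9%.

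**Figure D4:**
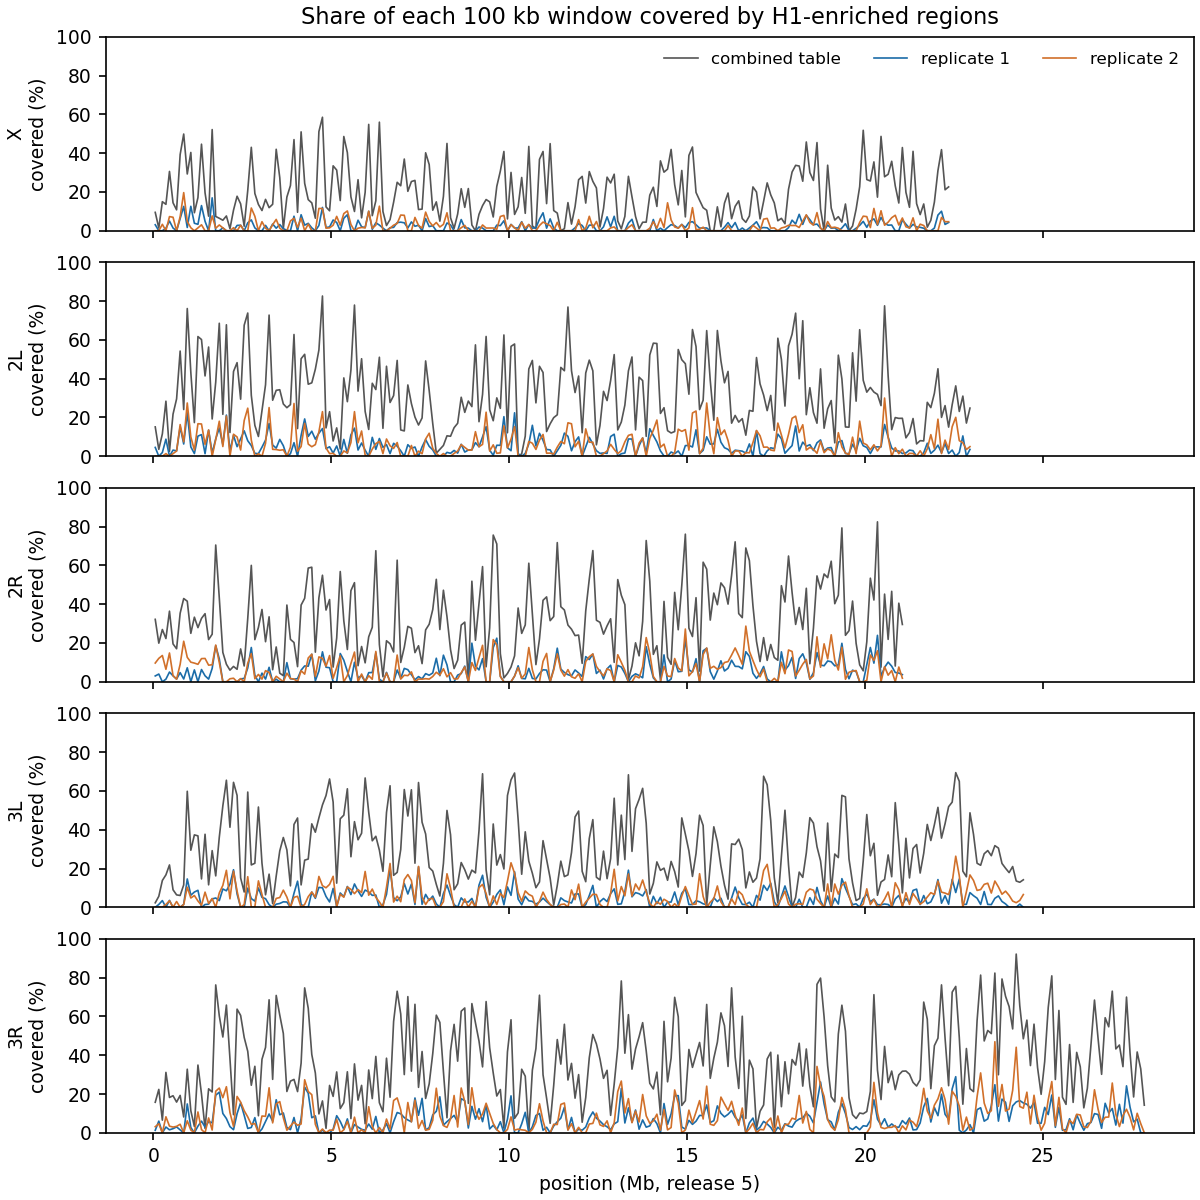
The share of each 100 kb window covered by H1-enriched regions, in percent, against its position in Mb on the 5 arms, for the combined table and both replicates. The window of 3R from 23600001 to 23700000 was covered to 24.8% in replicate 1, 47.0% in replicate 2 and 82.4% in the combined table.

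The decline on 3R rested on replicate 1: that replicate alone gave rho of -0.83 (permutation test, adjusted p = 0.0172) and replicate 2 alone -0.54 (adjusted p = 0.564), while 20 windows gave -0.41 (adjusted p = 0.245) and the combined table -0.61 (adjusted p = 0.328). Replicate 1 alone also passed the threshold on 2L and 2R (rho of -0.78 on each, permutation test, adjusted p = 0.0172), where replicate 2 alone gave -0.24 and -0.18 (adjusted p = 0.684 on each), and on 3L replicate 2 alone gave 0.15. Windows are not replicates, and neighbouring windows are not independent.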

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

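The alternatives with regions of at least 2000 bp, with heterochromatic and unplaced sequences alone, and with regions moved within 50 kb were chosen after seeing the data. Every overlap, between the replicates and with the combined table, stayed above chance and past the threshold in each alternative run. The excess was from 1.30 to 6.13 times chance. Random placement was run for the replicates alone. The combined table bears on the same libraries, so overlap with it is not independent evidence. The lowest excess came from moving regions within 50 kb, which gave chance values of 5.09% by length, 19.8% for replicate 1 and 16.3% for replicate 2, and 14.0% and 17.4% for combined regions overlapping replicates 1 and 2. The ratio of the X to the autosomal arms moved to 0.690 with scores at or above the median and 0.248 with regions of at least 2000 bp, and that of chromosome 4 to 0.0699 and 0. The 0.0699 is the mean of 0.105 in replicate 1, up from 0.0893, and 0.0346 in replicate 2, down from 0.0934. That of placed heterochromatin was 0.850 with scores at or above the median, against 0.521, within its wide spread, and replicate 2 went from 0.834 to 1.40; the cause was not tested. On 3R, rho was -0.41 with 20 windows, a weaker value whose cause was not tested. Leaving out each replicate in turn gave rho from -0.83 to -0.54 on 3R, from -0.78 to -0.24 on 2L, from -0.78 to -0.18 on 2R and from -0.56 to 0.15 on 3L. The strongest of these came from replicate 1 alone, where 2L and 2R passed the threshold, and the reversed value on 3L from replicate 2 alone; the cause was not tested. A minimum of 1000 bp removed no region and tested nothing. The settings fixed beforehand for gene features, gene lists and base composition were not run, since no annotation or sequence of Release 5 was used here. No paired analysis was possible because only the ChIP samples were analysed, so no groups that share replicate numbers were compared. Read depth is unknown, which limits any comparison of region numbers between lists.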

Other observations

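All tests in this part were chosen after the result was seen, and so were the 3 ways of choosing the constant behind the scores and the rule that an explanation is set aside only where every list and constant speaks against it. Combinations of list and constant reuse the same libraries, and their intervals are over regions, which are not replicates. A tally of such combinations is therefore not repeated evidence.

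Dense H1 windows recurred at the same positions in both replicates. Of 1189 windows of 100 kb on the 5 arms, 27 were among the densest 5% of both replicates, against a mean of 4.38 and a maximum of 16 in 100000 rotations (permutation p = 1e-05, the smallest possible). Of these, 16 lay on 3R and 0 on the X. The densest by replicate mean, 3R from 23600001 to 23700000, was covered to 24.8%, 47.0% and 82.4% in replicate 1, replicate 2 and the combined table, and 3R from 24200001 to 24300000 to 15.9%, 44.1% and 92.1%. Across windows, Spearman's rho between the replicates was 0.69 on all 5 arms, 0.74 on 3R and 0.52 on the X; windows are not independent replicates.

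At the other end, 10 of the windows held no region of the combined table, 6 of them on the X. The longest stretch without a combined region ran on the X from 15581641 to 15807621, or 226 kb. On chromosome 4 a stretch of 171 kb ran from 98715 to 269709. In the 1 of 10 windows of each arm next to the centromere, replicate 2 covered more than replicate 1 by 2.37 times on 2R, 2.35 on 3L, 1.87 on 2L, 1.35 on 3R and 1.22 on the X, while the median ratio of the other windows was from 1.03 to 1.19. On 2R and 3L no other window exceeded 1.30 and 1.39, whereas single windows elsewhere reached 1.86 on 2L, 1.34 on 3R and 1.51 on the X, so the proximal window stood apart on 2R and 3L.

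Unplaced and heterochromatic sequences were over-represented among the highest scores. Of the 50 highest-scoring regions, 23 in replicate 1, 43 in replicate 2 and 42 in the combined table lay off the main sequences, compared with 2.22%, 8.64% and 7.31% of all regions. Ratios of few counted units are a candidate explanation: over all regions, the upper term per kb off the main sequences was at most 0.725 of that on them in any list and with any constant, though this does not show that it set the scores. The median lower term of the 50 highest-scoring regions was 1 in the combined table, against 161 to 229 over all regions. It was 7.5 to 9 in replicate 2, against 71 to 106, and 18 to 57 in replicate 1, against 67 to 179. The highest scores thus had small lower terms with every constant, but these regions were picked by the ratio itself. A higher H1 ratio in heterochromatin stays open. Over all regions, median scores on placed heterochromatin were 0.610, 0.712 and 0.491 in replicate 1, replicate 2 and the combined table. Those on the autosomal arms were 0.529, 0.567 and 0.379. Over regions with a lower term above 100, the score difference in replicate 1 was -0.00348, -0.0294 (13 regions) and 0.036 with the 3 constants. It was 0.034 to 0.036 in replicate 2 and 0.08 in the combined table. This filter acts on a term of the score itself, which varies with the constant. The bootstrap interval lay above 0 in 4 of 7 distinct combinations of list and constant and below 0 in 1.

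Heterochromatin held more regions in replicate 2 than in replicate 1. An equal increase on all sequences in replicate 2 is argued against by its covered length. On placed heterochromatin this was 4.81 times that of replicate 1, and from 3.25 to 7.77 times on the 4 sequences. On the 5 arms it was 1.10 to 1.27 times. Because these values are the pattern itself, they show only that the increase was unequal. Read depth and threshold are unknown and could act unequally between sequences, so neither is argued against. A thinner lower term on heterochromatin in replicate 2 could not be decided: relative to the autosomal arms it was from 0.752 to 1.37 times that of replicate 1, with intervals that included 1 for each constant. No biological explanation was tested, since both replicates belong to 1 group.

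The X held fewer regions, with higher scores. A thinner lower term on the X may contribute: per kb it was from 0.698 to 0.8 of that on the autosomal arms, but in 1 of 7 distinct combinations of list and constant the interval reached 1.02, and its upper bound fell on either side of 1 with different bootstrap seeds, so this explanation stays open. Lower H1 along the whole X also stays open. Within 5 equal classes of the lower term, scores on the X were higher than on the autosomal arms by 0.0593 to 0.0881. The bootstrap interval lay above 0 in all 7 distinct combinations. All these regions had passed a threshold that is not known, so the comparison cannot count against lower H1 on the X. With 2 of the 3 constants of replicate 1, these classes also left the lower term per kb unmatched by over 10%. These terms are known for called regions alone, so sequence of the X without a called region is not covered. Noisier ratios could also raise the score of called regions, which was not tested.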
